A study of Homo sapiens with 10 samples.

How the data were processed

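The series held 10 samples from cultures labelled as the breast cancer line MCF7. They were a TRIM28 chromatin immunoprecipitation library with its input, and 8 RNA sequencing libraries in 4 groups of 2. The labels give the molecule of all 10 samples as genomic DNA, and the 8 libraries were taken as RNA from their titles and the extraction protocol, which was not tested. The RNA groups were shEZH2, which carried a hairpin against EZH2, its control set shCtrl_EZH2, shTRIM28, which carried a hairpin against TRIM28, and its control set shCtrl_TRIM28. Per the labels' protocols, the hairpins were delivered with lentivirus, the depleted cells were kept as stable clones under puromycin, and the control virus carried a scrambled sequence. The labels name a single hairpin clone for both knockdowns and do not say how many cell clones were used. The 2 chromatin samples came without a count table and were not analysed.

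The deposited values were raw read counts per assembled locus for the 8 RNA libraries, with no normalization, and each locus carried an identifier and either a gene symbol or no symbol. CASAVA 1.8.2, Bowtie2 2.1.0, TopHat2 2.0.10, HTSeq 0.6.1p1 and the genome build hg19 were named per the submitters' processing notes, without their order or settings. How the loci were assembled and which strand setting was used for counting were not stated in the sources used here, and the table gave no coordinates, so none are printed. The values were checked to be whole numbers.

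The table held 71605 loci, of which 17411 named no gene. Loci without a symbol took between 1.30% and 1.93% of the counts of a library and were left out, apart from an alternative that kept them. Of the 54194 loci with a symbol, 22293 passed the filterByExpr function of edgeR with a minimum count of 10 and a minimum total of 15. A symbol stood on more than 1 locus in 1171 cases, and such loci were tested separately. Library totals lay between 43004379 and 75784400 counts, which made counting error small for most genes named here. Counting intervals and floors cover counting error only.

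Counts were analysed in R 4.3.3 with edgeR 4.0.16, using trimmed-mean (TMM) scaling, 1 mean per group over the 8 libraries, and the quasi-likelihood test, with 4 residual degrees of freedom. Each knockdown was compared with its own control set. The difference between the knockdown effects and the difference between the control sets were tested as further contrasts of the same model. Adjusted p-values were Benjamini-Hochberg values over all tested genes, and a gene was called at an adjusted p under 0.05. Errors printed beside log2 fold changes are standard errors computed from the fold change and its quasi-likelihood F statistic, with n = 2 libraries per group. The spread behind them was pooled over all 8 libraries and moderated across genes with 13.9 prior degrees of freedom. They are therefore not the spread of the compared libraries alone. CPM values are group means of counts scaled to the TMM-adjusted library size. Nothing in the labels says that replicates were separate cultures, so the p-values measure only the spread between these libraries. With 2 libraries per group, no regrouping of the samples can reach a share under 0.05, and none was counted. Where a group held 0 counts, the fold is a lower bound against a floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio is given with its 95% counting interval from an exact Poisson test.

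Before the data were examined, the contrasts, the alternatives and 32 gene lists were fixed. The lists were PRC2 subunits, SWI/SNF subunits, TRIM28 partner heterochromatin factors, mammosphere and stem cell genes, Notch pathway, Wnt targets, mesenchymal genes, epithelial genes, luminal and estrogen response genes, basal and myoepithelial genes, mitotic genes, DNA replication genes, p53 targets, cell cycle inhibitors, interferon-stimulated genes, MHC class I and antigen presentation, NF-kB and cytokine genes, HOX genes, developmental Polycomb targets, imprinted genes, protocadherin cluster genes, zinc finger genes, cancer-testis and germline genes, hypoxia and glycolysis genes, cholesterol synthesis genes, unfolded protein and amino acid stress genes, autophagy and AMPK genes, cytosolic ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, fibroblast markers, and blood and endothelial markers. Each list was tested with camera from edgeR and limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. The test was repeated with the correlation estimated per list, and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. With an estimated correlation, camera rests on the 4 residual degrees of freedom, so few of the 32 lists could pass. A call lost there does not show that correlation between genes undid it. For the basal genes in shEZH2 the estimated correlation was -0.0033, below the preset, yet the unadjusted camera p went from 0.0031 to 0.031.

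The rule for named genes was also fixed in advance. It took EZH2 and TRIM28 in each library, then for each knockdown the 10 largest rises and 10 largest falls among called genes with a mean CPM of at least 5 in the higher group and no overlap between knockdown and control libraries. It also took up to 4 called members per list with the largest change, or the 2 most abundant members of a list with fewer than 2 called. For genes changed the same way in both knockdowns it took 10 per direction, and for the difference between the knockdowns 5 per direction. Members of this set could be left out, and 1 gene among the 10 largest falls in shTRIM28 is not reported here. Genes named in the comparison of the control sets, heat shock genes and neighbours of HCFC1 were chosen after values had been seen. The 9 sets of cell type markers for that comparison were written after the level of KRT8 was known.

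The model was run on counts simulated independently per gene from the means, library sizes and fitted dispersions of the 22293 genes, with 200 genes changed per comparison. The changed genes were drawn only from those above a floor of control level, so the shares do not describe the lowest genes. The counts came from the model's own spread and few genes changed. The run therefore checks the workings of the test, and could not test the scaling or the fit of the model to the data. For shEZH2, 76.1% of genes changed by 0.5 on the log2 scale were recovered, 95.5% of those changed by 1 and 100% of those changed by 2, with 20 false calls. For shTRIM28, the shares were 74.6%, 94.0% and 100%, with 12 false calls.

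The alternatives fixed in advance were the size factors of DESeq2 1.42.0 used inside edgeR, library totals alone, no filter on low counts, a filter at a mean CPM of 5, the Wald test of DESeq2, limma-voom, a fit per experiment, the replicate number as a block, a minimum absolute log2 fold change of 1, an adjusted p under 0.01, and leaving out each library in turn. Added after seeing the data were keeping loci without a symbol, removing small structured RNA loci, and restricting the overlap to genes with a mean CPM of at least 5 in both control sets. A RefSeq gene table of a different build than the files was used only for gene names and for which genes neighbour each other. It placed 444 of the 468 measured zinc finger genes.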

Results

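The data comprised 8 RNA sequencing libraries from cultures labelled as MCF7, an estrogen receptor positive line of luminal breast cancer cells. The groups shCtrl_EZH2, shEZH2, shCtrl_TRIM28 and shTRIM28 held 2 libraries each. Total counts were 61937059 and 60595271 in the shCtrl_EZH2 libraries and 63162064 and 75784400 in the shEZH2 libraries. They were 48635170 and 45252580 in the shCtrl_TRIM28 libraries and 48755360 and 43004379 in the shTRIM28 libraries. Small structured RNAs, such as the RNA of the signal recognition particle, took between 13.1% and 29.6% of the counts, and their share differed between replicates. It was 15.5% and 13.1% in the shCtrl_EZH2 libraries and 21.0% and 16.6% in the shEZH2 libraries, which did not overlap, and 19.3% and 27.8% in the shCtrl_TRIM28 libraries and 29.6% and 16% in the shTRIM28 libraries, which did. The knockdown experiments did not share controls. Spearman correlations across genes were at least 0.979 between libraries of an experiment and between 0.786 and 0.804 across the experiments. The first principal component, which parted the experiments, held 89.9% of the variance.

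The TRIM28 transcript, which encodes a corepressor recruited to chromatin by zinc finger proteins, was strongly reduced by its hairpin. Its level fell from 183 and 178 CPM in the shCtrl_TRIM28 libraries to 44.8 and 45.8 CPM in the shTRIM28 libraries, a log2 fold change of -1.99 ± 0.0555 (SE, n = 2 per group, adjusted p = 7.65e-15). The EZH2 transcript, which encodes the histone H3 lysine methyltransferase of Polycomb repressive complex PRC2, was less clearly reduced by its own. It stood at 51.0 and 35.2 CPM in the shCtrl_EZH2 libraries and at 39.5 and 21.9 CPM in the shEZH2 libraries, so that the groups overlapped. The SD of its log2 CPM within these groups was 0.501, so the pooled error printed next understates their spread. The log2 fold change of EZH2 was -0.50 ± 0.176 with an adjusted p of 0.0308, and over the alternatives the adjusted p ranged from 5.79e-11 to 0.712. The call of EZH2 was lost without shCtrl_EZH2 replicate 1 (-0.16) and without shEZH2 replicate 2 (-0.08), and also with the Wald test of DESeq2 (-0.48, adjusted p = 0.324), with the filter at a mean CPM of 5 (-0.49) and with the fit per experiment (-0.45). Without shEZH2 replicate 1 the fall of EZH2 was larger, at -0.97. With the replicate number as a block, EZH2 changed by -0.52 (quasi-likelihood test, adjusted p = 1.13e-05), but replicate numbers were not shown to pair the libraries. The shEZH2 libraries are therefore named by their label, and a fall of the EZH2 transcript in them was not secured by these counts. In shTRIM28, EZH2 changed by -0.11 ± 0.184 (adjusted p = 0.704). TRIM28 was higher in the shEZH2 libraries, at 0.39 ± 0.0513 (adjusted p = 7.21e-06), a call lost with library totals alone (0.27, adjusted p = 0.154), the adjusted p ranging from 4.71e-12 to 0.154 over the alternatives.

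**Figure D1:**
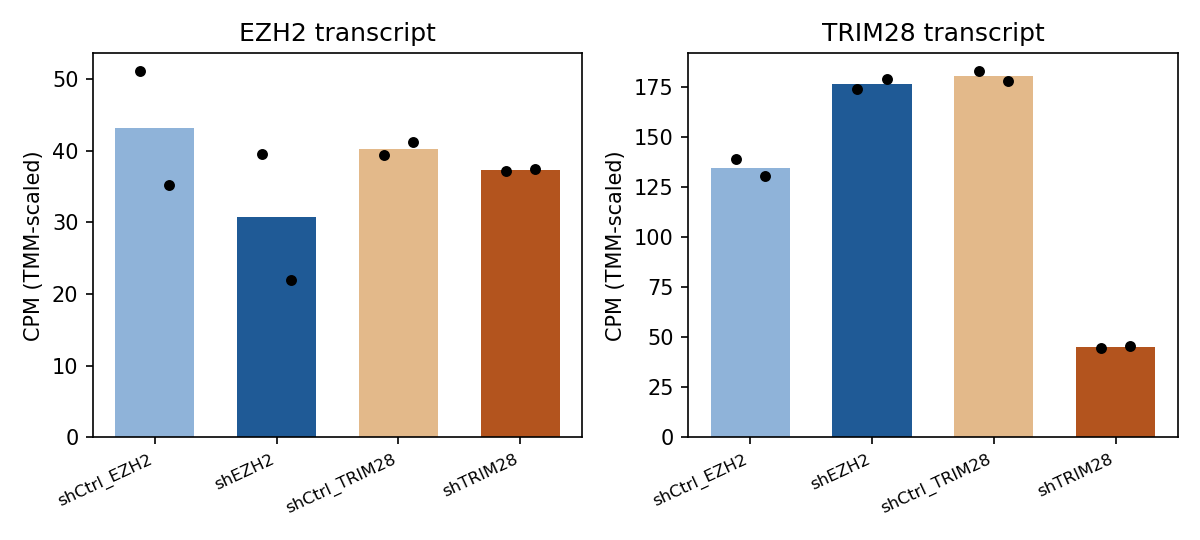
Level of the EZH2 and TRIM28 transcripts in CPM (TMM-scaled) by group; bars are means of the 2 libraries and points are single libraries. TRIM28 lay at 44.8 and 45.8 CPM in shTRIM28 against 183 and 178 CPM in its controls, while the EZH2 levels of shEZH2 and its controls overlapped.

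Both control sets carried a control hairpin and the same cell line label, so their comparison measures how far the experiments differed before any knockdown. Most transcripts of luminal breast cells were far lower in the EZH2 controls than in the TRIM28 controls. KRT8, a keratin of simple epithelia, stood at 9.98 CPM in the EZH2 controls and 8077 CPM in the TRIM28 controls, and KRT19, another such keratin, stood at 0.107 and 2048 CPM. ESR1, the estrogen receptor, stood at 1.27 against 522 CPM, its target TFF1 at 0.0423 against 1192 CPM, and CDH1, which encodes E-cadherin, at 3.69 against 649 CPM. In the opposite direction, the intermediate filament gene VIM stood at 319 CPM in the EZH2 controls and 5.35 CPM in the TRIM28 controls, the neurofilament gene NEFM at 236 against 0 CPM, and LIN28B, which encodes a regulator of let-7 microRNAs, at 218 against 0.139 CPM. Of 16 luminal breast markers, 6 reached 5 CPM in the EZH2 controls and 16 did so in the TRIM28 controls. The corresponding counts were 6 and 2 of 12 fibroblast and mesenchymal markers, 5 and 3 of 12 neural markers, 4 and 1 of 8 kidney developmental markers, 3 and 2 of 9 pluripotency markers, and 1 and 1 of 7 melanocyte markers. They were 0 and 0 of 14 erythroid and megakaryocytic markers, 0 and 2 of 14 lymphoid and myeloid markers, and 0 and 1 of 10 hepatocyte markers. MUC1, a mucin also found in luminal cells, stood at 94.6 and 92.0 CPM (log2 difference 0.04, adjusted p = 0.511). In all, 17187 genes differed, 8660 higher and 8527 lower in the EZH2 controls, and 10512 of them by at least 2-fold. Of the called genes, 50.4% were higher in the EZH2 controls in the main setting, and over the alternatives 48.6% (without shCtrl_EZH2 replicate 1) to 63.9% (library totals alone, which moved the median log2 difference of all genes to 0.42).

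**Figure D2:**
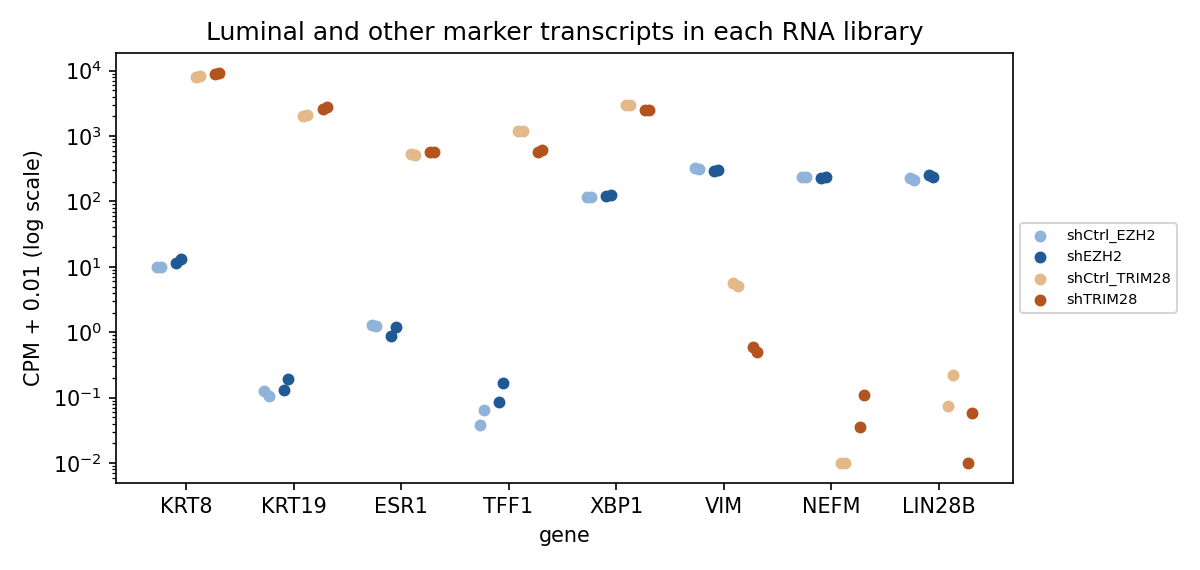
Level of 8 marker transcripts in each of the 8 RNA libraries, as CPM + 0.01 on a log scale; each point is a library and colours give the group. The luminal genes KRT8, KRT19, ESR1, TFF1 and XBP1 were lower in the libraries of the EZH2 experiment, and VIM, NEFM and LIN28B were lower in those of the TRIM28 experiment.

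The comparison of shEZH2 with its controls asks what differed in cells with the hairpin against EZH2. As the labels describe stable clones, differences between clones were not separable from an effect of the hairpin. Most mitotic genes measured rose in shEZH2, while most histone, DNA replication and p53 target genes fell. Of 28 mitotic genes measured, 25 rose and none fell, among them CDC20, an activator of the anaphase-promoting complex (log2 fold change 1.03 ± 0.0599), and CCNB1, which encodes cyclin B1 (0.82 ± 0.0510). Of 35 DNA replication genes, 31 fell and 1 rose, among them the DNA ligase gene LIG1 (-1.24 ± 0.106) and the helicase subunit gene MCM6 (-1.06 ± 0.0573). Of 28 p53 targets, 24 fell and none rose, among them DDB2, a DNA damage recognition gene (-1.64 ± 0.0918), and TP53INP1 (-1.54 ± 0.0625). Of 64 replication-dependent histone genes, 46 fell and none rose, among them HIST1H2BL (-1.32 ± 0.0682). The camera adjusted p was 4.58e-17 for the mitotic genes, 4.09e-15 for the DNA replication genes, 1.14e-22 for the p53 targets and 5.51e-20 for the histones. With an estimated correlation, the adjusted p was 0.177 for the mitotic genes and the p53 targets and 0.277 for the other 2 lists. Adjusted over the list alone, 25 mitotic genes rose, 31 replication genes fell, 25 p53 targets fell, and 47 histones fell while 1 rose. Whether the make-up of the libraries contributed to the fall of the histones was not tested.

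Among genes with a mean CPM of at least 5 in the higher group and no overlap between the groups, the largest rise in shEZH2 was that of ZCCHC12, a zinc knuckle gene, from 12.7 to 58.6 CPM (2.21 ± 0.0810, adjusted p = 2.08e-12). Chaperone genes known from the heat shock response were also among the 10 largest rises, with HSPA1A rising from 398 to 1372 CPM (1.79 ± 0.0608), HSPA8 from 2197 to 6192 CPM (1.50 ± 0.0751) and DNAJB1 from 76.7 to 199 CPM (1.38 ± 0.0506). HSPA1B rose by 1.71 ± 0.0625, but HSPA1A and HSPA1B are near-identical copies, so the split of reads between them is uncertain. Other large rises were those of TNFRSF12A, a receptor of the TNF family (1.70 ± 0.110), CLU, which encodes the secreted chaperone clusterin (1.67 ± 0.0831), HCFC1, a transcriptional cofactor (1.59 ± 0.0704), the spliceosomal RNA gene RNU4-2 (1.39 ± 0.227) and RRP12, a ribosome biogenesis gene (1.38 ± 0.0735). Small structured RNAs as a class took more of the counts in shEZH2, so the rise of RNU4-2 was not separable from the make-up of the libraries. Under the same limits, the deepest falls were those of TXLNB (-3.74 ± 0.202), C1orf95 (-3.47 ± 0.165), the glycosyltransferase gene GALNT5 (-2.85 ± 0.174) and the gap junction gene GJB2 (-2.44 ± 0.170). They were followed by the cholesterol exporter gene ABCA1 (-2.30 ± 0.159), the glutamate transporter gene SLC1A1 (-2.30 ± 0.167), LUM, which encodes the matrix proteoglycan lumican (-2.26 ± 0.212), LPPR4 (-2.16 ± 0.187), EMX2OS (-2.09 ± 0.203) and the adenylate kinase gene AK7 (-2.09 ± 0.172).

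Further fixed lists were called by camera in shEZH2 at the preset correlation but not with an estimated one. As background, 3803 of all 22293 tested genes were called higher in shEZH2 and 5232 lower. Of 22 SWI/SNF subunit genes, which encode a chromatin remodelling complex, 11 rose and 4 fell (camera adjusted p = 0.00335, and 0.407 with an estimated correlation), with BCL7B at 0.84 ± 0.0744, SMARCB1 at 0.70 ± 0.0653 and ARID1B at 0.69 ± 0.0629. Of 24 mammosphere and stem cell genes, 12 fell and 3 rose (adjusted p = 0.00335, and 0.277 with an estimated correlation), among them the chemokine receptor gene CXCR4, which fell from 31.4 to 11.1 CPM (-1.50 ± 0.0888), and the growth regulator gene MYC, which fell from 226 to 101 CPM (-1.16 ± 0.0558). Of 21 Notch pathway genes, 13 fell and 3 rose (adjusted p = 0.0263, and 0.525 with an estimated correlation), among them the coactivator gene MAML2 (-1.94 ± 0.178) and the receptor gene NOTCH3 (-1.27 ± 0.115). The call of the Notch list was lost without shCtrl_EZH2 replicate 1 (adjusted p = 0.144) and without shEZH2 replicate 2 (adjusted p = 0.0762), its adjusted p ranging from 0.00661 to 0.525 over the alternatives for camera. Of 22 basal and myoepithelial genes, 11 fell and 1 rose (adjusted p = 0.00985, and 0.277 with an estimated correlation), with the P-cadherin gene CDH3 at -2.37 ± 0.241 and the smooth muscle actin gene ACTA2 at -1.26 ± 0.220. Of 35 interferon-stimulated genes, 11 fell and none rose (adjusted p = 0.00335, and 0.277 with an estimated correlation), with IFI44L at -3.80 ± 0.326 and IFIT1 at -1.51 ± 0.150. Of 29 hypoxia and glycolysis genes, 15 fell and 3 rose (adjusted p = 8.87e-05, and 0.525 with an estimated correlation), with the stress-induced mTOR inhibitor gene DDIT4 at -1.35 ± 0.0581 and NDRG1 at -1.19 ± 0.0647. Of 11 fibroblast markers, 8 fell and 2 rose (adjusted p = 0.00445, and 0.277 with an estimated correlation), including LUM. Adjusted over the list alone, the counts that rose and fell were 13 and 4 for SWI/SNF, 4 and 12 for mammosphere genes, 3 and 13 for Notch, 2 and 11 for basal genes, 0 and 11 for interferon-stimulated genes, 3 and 17 for hypoxia genes, and 2 and 8 for fibroblast markers.

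The lists of genes known as PRC2 targets did not pass the test in shEZH2. Of 57 developmental Polycomb targets, 12 rose and 16 fell (camera adjusted p = 0.791), and of 26 HOX genes, 6 rose and 3 fell (adjusted p = 0.566). Among 11 PRC2 subunits, 2 rose and 5 fell (adjusted p = 0.155), with EZH1, the paralog of EZH2, at -0.71 ± 0.0640 and RBBP4 at -0.56 ± 0.0508. Among 22 TRIM28 partner heterochromatin factors, 5 rose and 8 fell (adjusted p = 0.442), with CBX5, which encodes the heterochromatin protein HP1 alpha, at -0.75 ± 0.0612 and the DNA methyltransferase gene DNMT3A at -0.73 ± 0.0590. In the luminal and estrogen response list, 6 of 37 genes rose and 16 fell (adjusted p = 0.209), and in the epithelial list 1 of 25 rose and 7 fell (adjusted p = 0.415). In each list 3 genes held no counts in a group of this comparison. TFF1, among the luminal genes that rose, stood at only 0.0423 CPM in the controls and 0.118 CPM in shEZH2. Of the 25 epithelial genes, 24 were lower and 1 was higher in the EZH2 controls than in the TRIM28 controls. Among cell cycle inhibitors 3 of 13 rose and 6 fell, with CDKN1A, which encodes p21, falling from 36.5 to 13.8 CPM (-1.40 ± 0.0668). The counts that rose and fell were 3 and 9 of 18 Wnt targets, 4 and 6 of 24 mesenchymal genes, 1 and 5 of 16 MHC class I genes, 6 and 7 of 23 NF-kB and cytokine genes, 2 and 9 of 24 imprinted genes, 1 and 1 of 13 protocadherin genes, and 114 and 78 of 468 zinc finger genes. They were 0 and 3 of 12 cancer-testis genes, 9 and 5 of 23 cholesterol synthesis genes, 3 and 9 of 25 unfolded protein and amino acid stress genes, 5 and 8 of 24 autophagy genes, 23 and 7 of 74 ribosomal protein genes, and 1 and 1 of 8 blood and endothelial markers. None of 3 mitochondrially encoded genes was called, with MT-ND5 at -0.20 and MT-CYB at 0.19. The lowest camera adjusted p among these lists was 0.0716, for the zinc finger genes.

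Across all tested genes, 9035 differed between shEZH2 and its controls, 3803 higher and 5232 lower, and 257 rose and 1275 fell by at least 2-fold. The balance of rises and falls depended on the setting, with 42.1% of the called genes higher in the main setting and 17.6% to 50.3% over the alternatives. The low end came with library totals alone, which moved the median log2 fold change of all genes to -0.16, and the high end without shCtrl_EZH2 replicate 1. The share was 49.2% with the fit per experiment, 49.3% with the filter at a mean CPM of 5 and 49.4% with small structured RNA loci removed. An excess of falls among all called genes was therefore not secured. The counts at 2-fold, where falls outnumbered rises by far, were not repeated under the other settings. Of the 32 lists 11 were called, and none of these calls held with an estimated correlation.

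Knockdown of TRIM28 addresses which transcripts depend on this corepressor. Zinc finger genes and antigen presentation genes were called higher more often than lower in shTRIM28. Histone, DNA replication and stem cell genes were called lower more often than higher. With an estimated correlation, none of these 5 list calls held, the adjusted p lying between 0.333 and 0.476. Of 468 zinc finger genes, many of which encode the KRAB proteins that recruit TRIM28, 166 rose and 68 fell (camera adjusted p = 0.000146, and 0.333 with an estimated correlation; 168 and 73 adjusted over the list alone). ZNF716 rose from 1.82 to 58.9 CPM (5.0 ± 0.130, adjusted p = 2.99e-15), ZNF788 by 4.93 ± 0.293 and ZNF676 by 4.49 ± 0.389. ZNF729 held 2 counts in the controls and was 217 times as high in shTRIM28 (95% counting interval 59.8 to 1799.6). Of 16 genes of MHC class I and antigen presentation, 12 rose and none fell (adjusted p = 2.16e-05, and 0.333 with an estimated correlation; 14 rose adjusted over the list alone). HLA-A rose from 43.5 to 76.9 CPM (0.82 ± 0.0710), NLRC5, the transactivator of these genes, from 0.253 to 1.15 CPM (2.19 ± 0.413), and the immunoproteasome gene PSMB8 by 1.39 ± 0.307.

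By the rule for named genes, the largest changes in shTRIM28 included several genes with few or no counts in the lower group. The transcript RP11-402M4.1 had no counts in the controls and 11.1 CPM in shTRIM28, at least 308-fold higher, and RP11-10A2.1 was at least 177-fold higher. APOD, which encodes a lipocalin, rose from 4.13 to 109 CPM (4.71 ± 0.102, adjusted p = 5.85e-16), SPAM1, a sperm hyaluronidase gene, by 4.76 ± 0.273, RP11-384J4.2 by 4.25 ± 0.305, and AKAP6, which encodes a kinase anchoring protein, by 4.23 ± 0.235. FAM5C went from 12.3 CPM to no counts, at least 326-fold lower, and RPL35AP31, a ribosomal protein pseudogene, was at least 151-fold lower. GUCY1A3, a subunit gene of soluble guanylate cyclase, went from 33.3 CPM to 1 count, a ratio of 0.000378 (95% counting interval 9.56e-06 to 0.00211). GPR179 changed by -5.52 ± 0.249, C9orf152 by -5.20 ± 0.379, the kinesin adaptor gene SYBU by -5.03 ± 0.117, the nectin gene PVRL3 by -4.61 ± 0.117, the sulfatase gene SULF1 by -4.44 ± 0.137 and PLCXD3 by -4.42 ± 0.204. The labels describe the depleted cells as stable clones, and differences between clones were not separable from the knockdown here.

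Of 24 mammosphere and stem cell genes, 11 fell and 5 rose in shTRIM28 (adjusted p = 0.00616, and 0.333 with an estimated correlation). SOX2, a pluripotency factor gene, fell from 61.7 to 6.65 CPM (-3.21 ± 0.0940), CXCR4 from 21.4 to 3.43 CPM (-2.64 ± 0.115) and the receptor gene KIT from 2.20 to 0.819 CPM (-1.43 ± 0.190). That list's call was lost without shCtrl_TRIM28 replicate 2 (adjusted p = 0.0559) and without shTRIM28 replicate 2 (adjusted p = 0.0589), its adjusted p ranging from 0.000679 to 0.333 over the alternatives for camera. Of 18 Wnt targets, 7 fell and 2 rose (adjusted p = 0.0119, and 0.442 with an estimated correlation), among them the feedback inhibitor gene AXIN2 (-2.45 ± 0.132) and TNFRSF19 (-4.24 ± 0.307). Among the settings that leave out a library, the Wnt call was lost without either library of shCtrl_EZH2 or of shEZH2 and without shCtrl_TRIM28 replicate 1 (adjusted p from 0.0589 to 0.0696) and without shTRIM28 replicate 2 (adjusted p = 0.0883), the adjusted p ranging from 0.00192 to 0.442 over the alternatives for camera. Of 22 basal and myoepithelial genes, 10 fell and 3 rose (adjusted p = 0.00703, and 0.333 with an estimated correlation), with the keratin gene KRT6A at -3.53 ± 0.451. Of 64 histone genes, 55 fell and none rose (adjusted p = 1.99e-21, and 0.375 with an estimated correlation), with HIST1H2BB at -1.64 ± 0.126. Of 35 DNA replication genes, 21 fell and 1 rose (adjusted p = 2.65e-06, and 0.476 with an estimated correlation), with PCNA, the sliding clamp gene, at -0.71 ± 0.0609. Of 28 mitotic genes, 14 fell and none rose (adjusted p = 0.00489, and 0.476 with an estimated correlation), with the kinase gene AURKB at -0.64 ± 0.0715 and TPX2 at -0.58 ± 0.0523. Of 23 cholesterol synthesis genes, 12 fell and none rose (adjusted p = 0.0185, and 0.467 with an estimated correlation), with DHCR7 at -0.38 ± 0.0537. The call of the cholesterol list was also lost with library totals alone (adjusted p = 0.0851), and its adjusted p ranged from 0.00291 to 0.467 over the alternatives for camera. Of 25 unfolded protein and amino acid stress genes, 11 fell and 4 rose (adjusted p = 0.0446, and 0.333 with an estimated correlation), with PHGDH, the first enzyme gene of serine synthesis, falling from 22.7 to 3.63 CPM (-2.65 ± 0.0798). The call of this list was lost with each other scaling, with an estimated correlation and without any single library, with an adjusted p from 0.0520 to 0.333. Adjusted over the list alone, the counts that rose and fell were 5 and 12 for mammosphere genes, 2 and 8 for Wnt targets, 3 and 12 for basal genes, 0 and 56 for histones, 1 and 21 for replication, 0 and 15 for mitosis, 0 and 14 for cholesterol synthesis, and 4 and 11 for the stress genes.

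**Figure D3:**
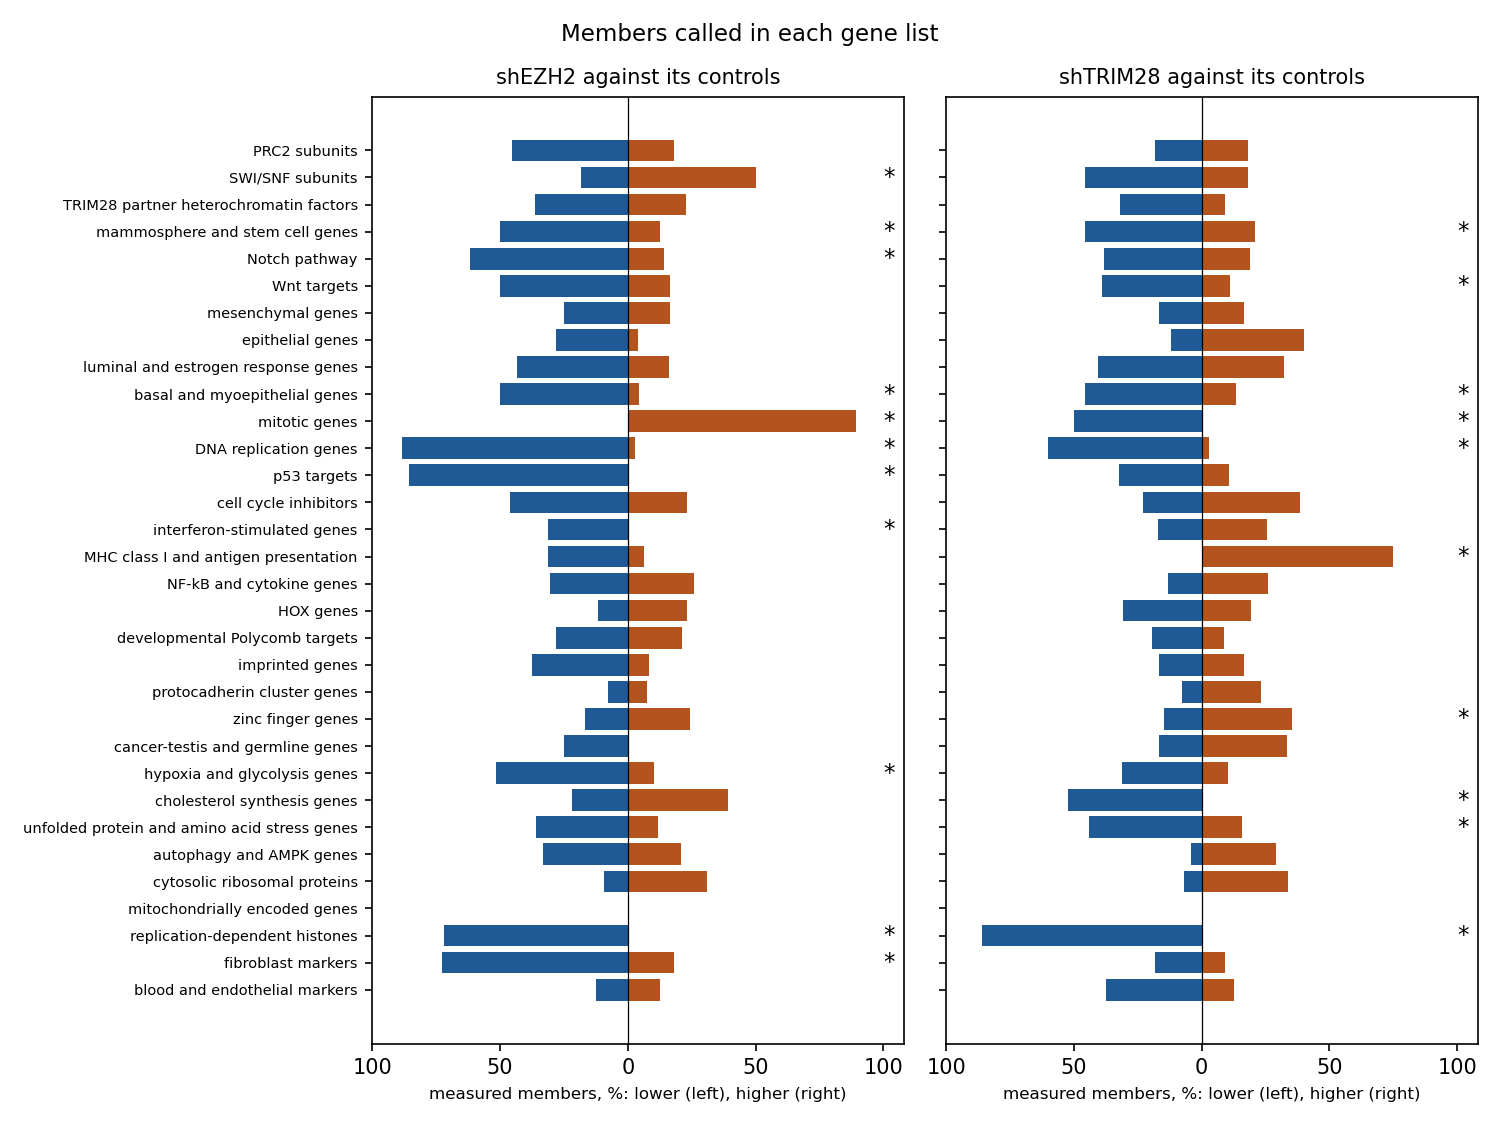
Percent of the measured members of each of the 32 fixed gene lists called lower (left, blue) and higher (right, orange) in shEZH2 and in shTRIM28 against their own controls; an asterisk marks a camera adjusted p under 0.05 at the preset correlation. Mitotic genes were called higher in shEZH2 (25 of 28) and lower in shTRIM28 (14 of 28), while histone genes were called lower in both (46 and 55 of 64).

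The luminal and epithelial lists were not called in shTRIM28. Of 37 luminal and estrogen response genes, 12 rose and 15 fell (adjusted p = 0.895), with IGFBP5, an insulin-like growth factor binding protein gene, rising from 171 to 958 CPM (2.48 ± 0.119) and the trefoil factor gene TFF3 falling from 47.6 to 15 CPM (-1.66 ± 0.0860). Of 25 epithelial genes, 10 rose and 3 fell (adjusted p = 0.255), with CDH1 at 0.46 ± 0.0665. Of 24 mesenchymal genes, 4 rose and 4 fell (adjusted p = 0.667), with VIM at -3.31 ± 0.149 and TGFBI, a matrix protein gene, at 1.31 ± 0.0803. Among 11 PRC2 subunits, 2 rose and 2 fell (adjusted p = 0.828), with EZH1 at 0.68 ± 0.0750 and PHF19 at -0.77 ± 0.0759. Among 22 SWI/SNF subunits, 4 rose and 10 fell (adjusted p = 0.135), with SMARCB1 at -0.59 ± 0.0711 and PBRM1 at -0.56 ± 0.0531. The counts that rose and fell were 2 and 7 of 22 TRIM28 partner heterochromatin factors, 4 and 8 of 21 Notch genes, 3 and 9 of 28 p53 targets, 5 and 3 of 13 cell cycle inhibitors, 9 and 6 of 35 interferon-stimulated genes, 6 and 3 of 23 NF-kB and cytokine genes, 5 and 8 of 26 HOX genes, 5 and 11 of 57 developmental Polycomb targets, and 4 and 4 of 24 imprinted genes. They were 3 and 1 of 13 protocadherin genes, 4 and 2 of 12 cancer-testis genes, 3 and 9 of 29 hypoxia and glycolysis genes, 7 and 1 of 24 autophagy genes, 25 and 5 of 74 ribosomal protein genes, 0 and 0 of 3 mitochondrially encoded genes, 1 and 2 of 11 fibroblast markers, and 1 and 3 of 8 blood and endothelial markers. The lowest camera adjusted p among these lists was 0.105.

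Across all tested genes, 7400 differed between shTRIM28 and its controls, 3517 higher and 3883 lower, and 697 rose and 832 fell by at least 2-fold. Of the called genes, 47.5% were higher in the main setting, and over the alternatives 40.9% (library totals alone) to 51.5% (the filter at a mean CPM of 5). An excess of falls among all called genes was therefore not secured, and the counts at 2-fold were not repeated under the other settings. Of the 32 lists 10 were called, and none of these calls held with an estimated correlation. In 8 of the list results of the 2 knockdowns, all uncalled, the median, the mean and the tests differed in sign: mesenchymal, HOX, Polycomb, protocadherin, autophagy and blood lists in shEZH2, and cell cycle inhibitors and interferon-stimulated genes in shTRIM28.

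The title of the series concerns genes that TRIM28 and EZH2 activate together, which would be lower in both knockdowns. A fall of the EZH2 transcript was not secured in shEZH2. Most luminal transcripts were also far lower in its controls than in the TRIM28 controls. Genes lower in both are therefore given as values, and joint activation was not tested. CXCR4, named above, fell in both, as did the glutamate transporter gene SLC1A1 (-2.30 ± 0.167 in shEZH2 and -2.79 ± 0.173 in shTRIM28), the carbonic anhydrase gene CA2 (-1.81 ± 0.0945 and -4.06 ± 0.105), SULF1 (-1.34 ± 0.104 and -4.44 ± 0.137) and the growth factor receptor gene EGFR (-1.14 ± 0.0970 and -1.06 ± 0.125). Also lower in both were the transcription factor gene IKZF2, the adhesion gene CNTNAP2, the neuropeptide receptor gene NPY1R, CD109 and TMCC3. The co-chaperone gene BAG3 rose in both (1.08 ± 0.0589 and 1.17 ± 0.0524), as did LONRF2 (0.69 ± 0.0647 and 1.25 ± 0.0637), ZNF853, MST1L, AC005682.5, AC104135.3, and the spliceosomal RNA genes RNU5A-1, RNU5B-1, RNU5F-1 and RNU5A-8P, which are near-copies of each other and belong to the class that took more of the counts in shEZH2. In all, 1180 genes fell in both knockdowns where independent lists would share 911, and 660 rose in both where 600 were expected. Opposite changes also exceeded that number, with 1064 genes lower in shEZH2 and higher in shTRIM28 (825 expected) and 1022 the other way (662 expected).

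Among the 3926 genes called in both knockdowns, 1840 (46.9%) went the same way, an odds ratio of 0.716 (95% interval 0.629 to 0.816, Fisher's exact test across genes, which are not independent replicates). The correlation of the fold changes across genes was 0.0113 (Pearson) and -0.0137 (Spearman). In the 10205 genes with a mean CPM of at least 5 in both control sets, a restriction added after seeing the data, 798 fell in both (768 expected) and 575 rose in both (676 expected), and the correlation was 0.00879 (Pearson) and -0.0567 (Spearman). The knockdowns were set side by side here across control sets that differed in 17187 genes.

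**Figure D4:**
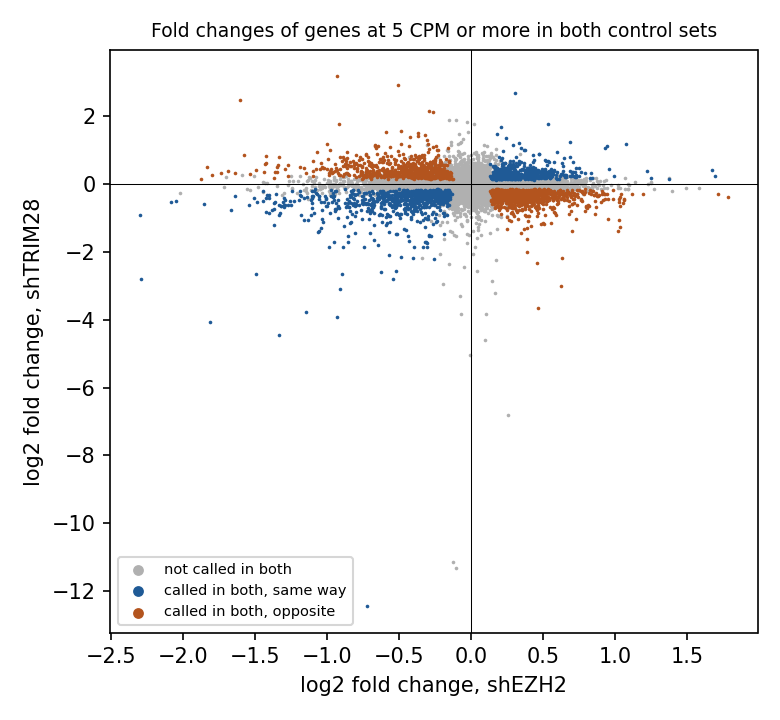
Log2 fold change in shEZH2 (horizontal axis) against that in shTRIM28 (vertical axis) for the 10205 genes with a mean CPM of at least 5 in both control sets; each point is a gene, coloured by whether it was called in both knockdowns. Of those called in both, 1373 went the same way and 1656 opposite ways; points below -10 on the vertical axis are genes with almost no counts in shTRIM28, whose fitted values are not measured folds.

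The difference between the knockdown effects was tested for each gene. TRIM28 itself differed (adjusted p = 1.74e-13), as did the guanylate cyclase genes GUCY1A3 and GUCY1B3, which encode the subunits of 1 enzyme. GUCY1A3 changed by -0.13 ± 0.0765 in shEZH2 (adjusted p = 0.203) and nearly vanished in shTRIM28, and GUCY1B3 changed by -0.78 ± 0.0954 in shEZH2 and went to no counts in shTRIM28, at least 112-fold lower. DACH1, a transcription factor gene, changed by 0.22 ± 0.0921 in shEZH2 (adjusted p = 0.0617) and was at least 75.3-fold lower in shTRIM28. In all, 8020 genes differed in their response, 3835 with a higher log2 fold change in shEZH2 and 4185 with a lower one. Of the called differences, 47.8% were higher in shEZH2 in the main setting, and over the alternatives 32.4% (library totals alone) to 53.3% (without shCtrl_EZH2 replicate 1), so the balance was not secured in direction. Because the control sets differed in their marker genes as well, a difference in response was not separable from a difference between the cultures.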

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

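Tests of the luminal transcripts were chosen after the result was seen, as were the Polycomb list test for EZH2 and the comparison of zinc finger genes between the knockdowns; the other tests here were written before.

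The test of the difference between the knockdown effects called 8020 genes, 3835 larger in shEZH2 and 4185 smaller. The adjusted p of the difference was 1.74e-13 for TRIM28, 8.55e-11 for FAM5C, 7.51e-10 for RPL35AP31, 1.90e-14 for GUCY1A3, 9.04e-10 for DACH1 and 1.17e-09 for GUCY1B3, all with a higher log2 fold change in shEZH2. With a lower log2 fold change in shEZH2, it was 0.000692 for BAI3, 0.00630 for HLA-DOA, 0.0163 for TRHDE-AS1 and 3.91e-10 for RAB34, and the first 3 of these had no counts in the TRIM28 controls. The changes of HLA-DOA and TRHDE-AS1 in shTRIM28 lost their call in several settings. With the fit per experiment, their quasi-likelihood adjusted p was 0.169 and 0.227. ZNF716 also differed (0.00699), with 3 or fewer counts per group in the EZH2 experiment. Of the fixed lists, the camera adjusted p of the difference was 0.00145 for SWI/SNF subunits, 2.88e-16 for mitotic genes and 0.00990 for cholesterol synthesis genes, which were higher in shEZH2 relative to shTRIM28. It was 0.0417 for luminal and estrogen response genes, 3.93e-13 for p53 targets, 0.0459 for interferon-stimulated genes and 0.000218 for MHC class I genes, which were relatively lower. With an estimated correlation none of these 7 lists held, the lowest adjusted p being 0.333. Among 15273 tested loci without a gene symbol, which the comparisons do not use, 681 were higher and 1041 lower in shEZH2, and 1576 were higher and 547 lower in shTRIM28.

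Luminal transcripts were far lower in the EZH2 controls than in the TRIM28 controls although both carry the same label. The KRT19 difference ranged over only 0.375 log2 units across 3 scalings, between -14.21 and -13.83. The TMM factors lay between 0.81 and 1.20, so a change of scaling could not have moved it far, and this check decides nothing. Depth or scaling is argued against by other genes, since it would shift the genes of a library alike. The mitotic and ribosomal lists had median log2 differences of only 0.21 and 0.12. A mixture of other cells with MCF7 cells is also argued against. The share of MCF7 cells could be at most 0.00856% by KRT19, 0.00777% by TFF1 and 0.0572% by AGR2. The epithelial list had a median log2 difference of -8.24, with 24 of 25 genes lower, while the mitotic and ribosomal medians lay at 0.21 and 0.12, which is consistent with cultures of the EZH2 experiment that were not luminal breast cells. Whether this came from another line or from a lasting change of the same line was not tested, and it stays a hypothesis found and tested on the same data.

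EZH2 fell by little in shEZH2 and its replicates stood apart. A spread shared by genes of this level in these libraries, which includes counting error, is argued against, as 0% of the 1000 genes nearest in level varied as much, with an SD of 0.501 for EZH2 and a median of 0.0591. The Polycomb target list, which loss of EZH2 function could raise, had a camera adjusted p of 0.791, which leaves that question undecided. What set the EZH2 transcript apart between replicates stays open.

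Zinc finger genes were called higher more often than lower in shTRIM28. Low expression is argued against, since 0% of 10000 lists matched on level reached the observed 70.9% of called genes that were higher. The matched lists had a median of 45.7%, the highest reaching 58.7%. They were drawn gene by gene and lack the correlation within a gene family, so the 0% may overstate how rare such a share is. A feature of these genes in any knockdown library stays open, as 59.4% were higher in shEZH2 (two-sided Fisher's exact p across genes = 0.0139). Zinc finger genes with none of their family among the 5 nearest genes on each side numbered 24 higher and 28 lower, or 46.2% higher, close to 46.8% of other called genes (two-sided Fisher's exact p across genes = 1), while clustered ones numbered 131 higher and 40 lower, so reads shared between paralogs could account for the rise. On chromosome 19, 95 of 208 were higher, against 60 of 236 elsewhere (two-sided Fisher's exact p across genes = 1.04e-05), which is also what a response of the clusters to loss of TRIM28 may give, and these explanations both stay open.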

How the results depend on the processing

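The alternatives that kept loci without a symbol, removed small structured RNA loci or restricted the overlap were chosen after seeing the data. Among genes called in the main setting and in an alternative, 0 changed direction in any contrast. With library totals alone, 5935 genes were called in shEZH2, 4040 in shTRIM28, 4709 for the difference and 814 the same way in both. With a minimum absolute log2 fold change of 1 the counts were 1532, 1529, 2260, 10512 between the control sets and 138 the same way in both, by construction. An adjusted p under 0.01 left 1107 genes the same way in both. The filter at a mean CPM of 5, which tests fewer genes, called 10544 between the control sets, and keeping loci without a symbol, which tests more, called 26834 and gave a correlation of -0.0149. Of the lists, 21 calls became 0 with an estimated correlation and 42 with fry, which asks another question. Leaving out 1 library, where the lone library is assumed to vary like the others, gave 7291 to 8981 genes in shEZH2, 5628 to 7579 in shTRIM28, 6981 to 7572 for the difference, 15923 to 17180 between the control sets, 1379 to 1708 the same way in both, 19 to 23 lists, and a correlation from -0.00564 (without shCtrl_TRIM28 replicate 2) to 0.0244. Except where construction is named, the cause was not tested. Replicate numbers were not shown to pair the libraries (correlations of the deviations -0.00787 and 0.0355 over all genes), and the replicate block gave 9088, 7485, 8111 and 1900 genes and 22 lists, with an adjusted p in shTRIM28 of 0.0982 for Wnt targets and 0.135 for the stress genes. Of 327 called effects of named genes, 60 lost the call in at least 1 setting, 212 of 5791 values in all, and 0 reversed, with EZH2 and TRIM28 in shEZH2 among the 60. Genes with few counts are limited by depth.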

Other observations

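The tests on heat shock genes and on the neighbours of HCFC1 were written before their results were seen, but both were prompted by genes already known to have risen. The rule that a median must pass its bound by more than its standard error was applied after the neighbours' value was seen.

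Heat shock chaperone transcripts rose together in shEZH2. Beyond the HSPA1A, HSPA8 and DNAJB1 genes that prompted the test, 16 of 18 further heat shock genes rose and 1 fell, with a median log2 fold change of 0.55. HSP90AA1, an inducible HSP90 gene, rose from 1282 to 2617 CPM (1.03 ± 0.0648), HSPH1 by 1.04 ± 0.0532, the co-chaperone gene STIP1 by 0.91 ± 0.0553 and CHORDC1 by 0.92 ± 0.0615, while HSPB1 changed by -0.36 ± 0.0834. The camera p was 1.24e-17 at the preset correlation and 0.00830 with an estimated correlation, both without adjustment over lists. Likewise unadjusted and with an estimated correlation, the camera p in shEZH2 was 0.00836 for p53 targets and 0.0111 for mitotic genes. The heat shock list therefore did not stand apart from those lists. In shTRIM28, 2 of the 18 heat shock genes rose and 8 fell. The list had a median of -0.12 and a camera p of 0.241 there. BAG3 and FKBP4 also belong to sets named in the report. The cells may have met a proteotoxic stress, but the design holds no test of what set it off.

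HCFC1 and IRAK1, which lie close together on their chromosome, rose by 1.59 and 1.25 ± 0.0579 (IRAK1 adjusted p = 3.81e-11) in shEZH2, IRAK1 being chosen after its value was seen. A gain in copy number might raise the genes around them as well. Of the 10 nearest tested genes outward of the pair, 5 rose and 1 fell, with log2 fold changes from -0.95 to 5.73. Their median was 0.199, just under the bound that had been written beforehand as counting against such a gain. The standard error of the median was 0.137 from the median absolute deviation, so under the later rule the test did not decide. The 1 gene lying between the pair was not among them.

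Changes of at least 16-fold in genes reaching 5 CPM were counted in each knockdown. There were 12 falls and 13 rises in shTRIM28, and 0 of either in shEZH2. In 3 of the falls and 3 of the rises the lower group held 3 or fewer counts.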
